A study of Arabidopsis thaliana with 32 samples.

How the data were processed

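The series holds stranded mRNA sequencing of whole Arabidopsis seedlings, about 40 seedlings per sample, in 32 libraries of 12 genotype-by-light groups, of which 8 have 3 libraries and 4 have 2. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.11, Bowtie2 2.2.2.0, SAMtools 0.1.19.0, HTSeq 0.6.0, edgeR 3.16.5 and the TAIR10 genome. The authors deposited a table of CPM (reads scaled by library size) for 19685 genes, and its values are treated here as a normalized signal, since the columns sum to 925942 to 1066829 and differ between libraries, as after scaling by an effective library size. The authors also deposited a table of log2 fold changes against hy5 for 9 comparisons, which is used here for 1 check. The plan had assumed plain CPM, and the test planned for them was kept. Each column is made of whole multiples of 1 step (within 0.01 reads), so the reads per gene were recovered from the steps for depth and for the count-based alternatives. Gene names came from a TAIR10.1 gene table, in which 19582 of the identifiers were found and 103 were not, and 8623 had a symbol. No coordinates, reads or alignments were used here.

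The libraries held 7499581 to 21420680 reads in these genes, on average 9001190 in dark OX and 17707000 in hy5 at 1.5 h. One read corresponds to 0.0457 to 0.131 CPM and a floor of 3 reads to 0.137 to 0.394 CPM, and these floors cover counting error only. Within groups, 28 pairs of replicates differed by 3.18 to 20.3 times the variance of counting alone.

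Python 3.11.15 prepared the tables and R 4.3.3 ran the tests. The main fit was limma 3.58.1 (lmFit, contrasts.fit, eBayes with trend) on log2(CPM + 1), with 1 mean per group over all 32 libraries, so that groups of 2 borrow the spread of the others. The p-values were adjusted by Benjamini-Hochberg within each comparison, and an adjusted p below 0.05 with no fold limit made a call. The planned filter, a CPM of at least 1 in at least 2 libraries, removed no gene. The 22 comparisons were each genotype against hy5 at the same light, 1.5 h or 4 h of light against dark within a genotype, the difference of the 1.5 h light response from that of hy5 (interaction), and VP16 against SRDX. Overlaps of called genes were set against independent lists, and the covariance of their differences against simulated groups with no change that share the same hy5 libraries. The fit was tested on simulated data made from these group means and spreads. For VP16 against hy5 in the dark it recovered 62, 88 and 98% of genes changed 1.5, 2 and 4-fold, and for SRDX against hy5 at 4 h 30, 70 and 100%, with 7 and 6 calls among 19485 unchanged genes.

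Before the data were examined, 17 gene lists with 291 genes were fixed, of which 279 were measured: light signalling regulators, B-box proteins, flavonoid and anthocyanin biosynthesis, photosynthesis apparatus, chlorophyll and carotenoid biosynthesis, photoprotection and DNA photorepair, circadian clock, auxin, cell wall, gibberellin and brassinosteroid, nitrogen and sulphur assimilation, dark and sugar starvation, and, as markers of stage, tissue and handling, seed storage, root hair and endodermis, heat shock, and defence, wounding and touch. Of the 291, 282 carry the listed name in the gene table and 9 go by another. Lists were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated per list. Called members are counted over all genes and, beside that, with p-values adjusted over the list alone.

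The genes named in the text follow a rule fixed at the same time. It takes HY5 and any light-signalling or B-box gene, the 4 called members of each other list with the smallest adjusted p in a comparison, and the 5 highest and 5 lowest called genes of each comparison with hy5 and of the light response in Col and hy5, with a mean of at least 5 CPM in the higher group and no overlap between libraries. For overlaps and interactions it takes the 5 largest under the same conditions. A list gene once named may be named in any comparison. Members of the LHCB1 family share sequence and their separate values are uncertain, as are those of CYP71A12, which has a close paralog.

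Whether replicate numbers pair the libraries was checked by correlating the deviations of same-numbered libraries from their group means. In Col against hy5 in the dark all 3 pairs correlated above 0.1 (0.172 to 0.306), and in no other comparison with 3 pairs did all of them. The labels give no shared batch or day. Alternatives were a pseudocount of 0.25, no filter, a fold of at least 2, a fit on the compared groups alone, median-of-ratios scaling, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, and each library left out in turn. A filter at a mean of 5 CPM, the light-signalling list without HY5, and direct comparisons with OX and the interaction at 4 h, each also with every library left out, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.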

Results

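RNA was sequenced from whole Arabidopsis thaliana seedlings of 5 genotypes, in 32 libraries that fall into 12 groups. The genotypes are the wild type Col, the mutant hy5, and 3 lines that express a tagged HY5 from the viral 35S promoter in the hy5 mutant. HY5 is a light-signalling bZIP transcription factor, and the labels do not name the hy5 allele. The line called OX here carries 35S:FLASH-HY5, the line VP16 carries the same protein fused to the VP16 transcriptional activation domain, and the line SRDX carries it fused to the SRDX repression motif. The seeds of all groups met 1 h of white light, given to start germination. Seedlings were then kept in the dark for 3 days, or were afterwards moved to white light of 100 µmol m−2 s−1 for 1.5 h or 4 h. Col, hy5, OX and VP16 have 3 libraries each in the dark and at 1.5 h. SRDX has 2 libraries in the dark, 2 at 1.5 h and 2 at 4 h, and hy5 has 2 at 4 h, so that 4 h holds these 2 genotypes alone. The libraries held 7499581 to 21420680 reads in the 19685 genes of the table, with a median of 14457454. Levels are given in CPM, reads scaled by library size, as mean ± SD, and differences as log2 of CPM + 1, ± standard error of the fit. The added 1 CPM draws differences at low levels toward 0, so there they are smaller than the fold between the printed means. A gene counts as higher or lower, risen or fallen, where its limma adjusted p lies below 0.05, and these p-values measure the spread between these samples.

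The transcript of HY5 (AT5G11260) was measured in every library first. Dark Col seedlings held 24.6 ± 4.68 CPM and dark hy5 seedlings 21.7 ± 2.52 CPM (SD, n = 3 each), so the mutant locus was still transcribed. After 1.5 h of light Col held 216 ± 14.2 CPM and hy5 25.1 ± 0.0243 CPM. OX held 14279 ± 2366 CPM in the dark and 9175 ± 1094 CPM at 1.5 h, VP16 2338 ± 350.4 and 2264 ± 138 CPM, and SRDX 1026 ± 79.7 and 783 ± 33.8 CPM (n = 2 each). At 4 h SRDX held 917 ± 11.7 CPM and hy5 82.2 ± 4.45 CPM (n = 2 each), and the rise in hy5 from the dark to 4 h was 1.88 ± 0.14. In the lines these reads come from the transgene and the mutant locus together. Every library of OX, VP16 and SRDX lay above every Col and hy5 library of the table.

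**Figure D1:**
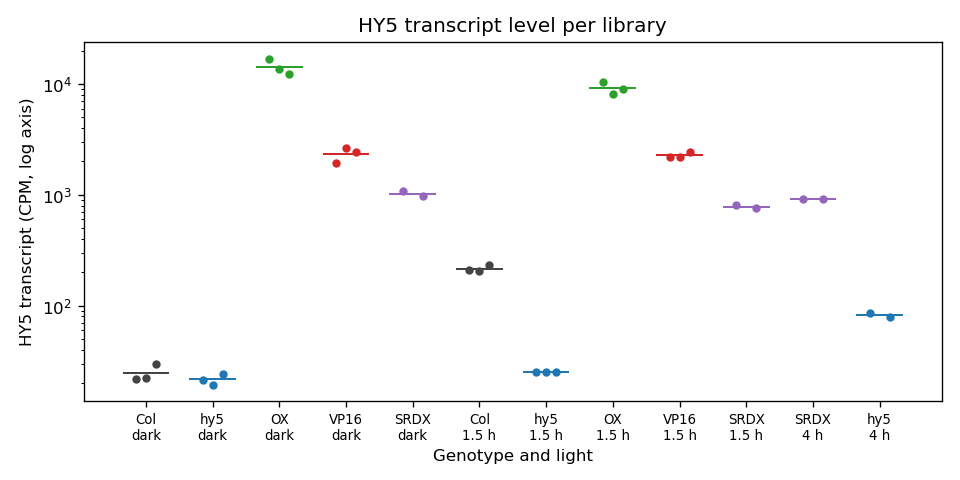
HY5 transcript level in each of the 32 libraries (points, CPM on a log axis) by genotype and light, with the group mean as a bar across. The lowest library of Col at 1.5 h lies at 207 CPM, and the 3 transgenic lines lie between 759.5 and 16907 CPM.

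Col against hy5 in the dark compares seedlings whose only light was that hour. The gene with the highest difference was EXPA2 (AT5G05290), an expansin that loosens cell walls, at 13.2 ± 2.93 CPM in Col and 1.73 ± 1.11 CPM in hy5 (log2 2.45 ± 0.33). HYH (AT3G17609), the closest homologue of HY5, was higher by 2.28 ± 0.15, at 5.44 ± 0.422 against 0.349 ± 0.328 CPM, and CHS (AT5G13930), chalcone synthase at the entry to flavonoids, by 1.8 ± 0.24. The largest fall was that of QQS (AT3G30720), a gene that affects starch content, at 0.519 ± 0.340 CPM in Col against 67.9 ± 2.56 in hy5 (log2 -5.53 ± 0.20), followed by MRD1 (AT1G53480), a gene first described in a methionine over-accumulating mutant, at -1.83 ± 0.18. Among clock genes PRR9 (AT2G46790) (-1.08) and PRR7 (AT5G02810) (-0.69) were lower in Col, and the clock list had 5 of 16 genes lower, or 6 adjusted over the list alone (camera, adjusted p = 3.5e-05; adjusted p = 0.22 with an estimated correlation). Light-harvesting genes were lower too, with 5 of the 40 photosynthesis genes called, or 10 lower and 1 higher adjusted over the list alone (camera, adjusted p = 8.2e-08; adjusted p = 0.49 with an estimated correlation), and the photoreceptor-interacting factors PIF4 (AT2G43010) (-0.72) and PIF5 (AT3G59060) (-0.46), which promote growth in the dark, were lower. Of 19685 genes, 169 were higher and 228 lower. That count depends on single libraries: it was 141 without dark Col replicate 1, 156 without replicate 2, 174 without dark hy5 replicate 2 and 159 without replicate 3, while it was 512 without dark Col replicate 3 and 303 without dark hy5 replicate 1. The 5 clock genes were 2 without dark Col replicate 1 and 3 without dark hy5 replicate 2, and the 5 photosynthesis genes were 3, 1 and 8 without dark Col replicate 1, 2 and 3 and 1 without dark hy5 replicate 3. The seed storage gene CRC (AT4G28520), a marker of stage, was higher in Col by 1.06 ± 0.23, at 1.74 ± 0.533 against 0.300 ± 0.149 CPM, and by 0.80 ± 0.23 at 1.5 h. It was not called in the dark without Col replicate 2 or hy5 replicate 2 or 3 (adjusted p = 0.0606, 0.0519 and 0.0745), nor at 1.5 h without Col replicate 1 or 2 or hy5 replicate 1 (0.0859, 0.107 and 0.153). Its list had 2 of 7 genes higher and 0 lower in the dark, or 3 and 0 adjusted over the list alone (camera, adjusted p = 7.4e-04; adjusted p = 0.22 with an estimated correlation). The 2 were 1 without Col replicate 1 or 3 or hy5 replicate 1, and 0 without Col replicate 2 or hy5 replicate 2 or 3.

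After 1.5 h of light Col stood above hy5 in genes of light protection and pigment. ELIP1 (AT3G22840), an early light-induced chlorophyll-binding protein, stood at 1560.3 ± 307 CPM in Col and 6.22 ± 0.682 CPM in hy5 (log2 7.74 ± 0.35). F3H (AT3G51240), flavanone 3-hydroxylase, was higher by 5.32 ± 0.19, CHS by 4.49 ± 0.24, at 229 ± 49.4 against 9.45 ± 3.25 CPM, and the ABC transporter subunits ABCI21 (AT5G44110) and ABCI20 (AT5G02270) by 5.13 ± 0.12 and 4.74 ± 0.09. The regulators of that pathway moved with it: MYB12 (AT2G47460), which drives flavonol genes, by 2.41 and MYB75 (AT1G56650), which drives anthocyanin genes, by 2.92. In the flavonoid list 16 of 23 genes were higher and 1 lower, or 17 and 1 adjusted over the list alone (camera, adjusted p = 5.4e-35; adjusted p = 1.2e-04 with an estimated correlation). All 7 genes of photoprotection and DNA repair were higher, and 7 adjusted over the list alone (camera, adjusted p = 1.4e-29; adjusted p = 1.1e-07 with an estimated correlation), among them CRY3 (AT5G24850), a DNA-repairing cryptochrome (3.52 ± 0.17), SIG5 (AT5G24120), a plastid sigma factor (3.05 ± 0.16), and GPX7 (AT4G31870), a plastid glutathione peroxidase (2.28 ± 0.18).

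Several genes that act on HY5 protein were themselves higher in Col at 1.5 h. COP1 (AT2G32950), the ubiquitin ligase that sends HY5 to degradation, was higher by 0.58 ± 0.09 and its partners SPA1 (AT2G46340) and SPA4 (AT1G53090) by 0.84 ± 0.12 and 1.05 ± 0.15. RUP1 (AT5G52250) and RUP2 (AT5G23730), which switch off the UV-B receptor, were higher by 3.64 ± 0.18 and 2.29 ± 0.22, and RUP1 stood at 164 ± 12 CPM in Col against 12.2 ± 0.849 in hy5. The phytochrome PHYB (AT2G18790) (0.70 ± 0.09) was higher as well, while PIF7 (AT5G61270) was lower (-1.04 ± 0.20). The light-signalling list had 10 of 29 genes higher and 5 lower, or 11 and 5 adjusted over the list alone (camera, adjusted p = 5.6e-05; adjusted p = 0.12 with an estimated correlation). The list holds HY5 itself, and without it 9 of 28 genes were higher and 5 lower, or 10 and 5 adjusted over the list alone (camera, adjusted p = 0.0012; adjusted p = 0.26 with an estimated correlation). B-box genes went both ways, with BBX22 (AT1G78600) (1.46 ± 0.13) and BBX24 (AT1G06040) (0.83 ± 0.10) higher and BBX25 (AT2G31380) (-0.67 ± 0.13) and BBX21 (AT1G75540) (-0.32 ± 0.09) lower, in a list with 3 of 15 higher and 2 lower, or 4 and 5 adjusted over the list alone (camera, adjusted p = 0.43; adjusted p = 0.59 with an estimated correlation). BBX21 was not called without Col replicate 1 or 2 at 1.5 h or without hy5 replicate 3 (adjusted p = 0.0537, 0.0862 and 0.0685).

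Transcripts of growth hormone genes differed at the same time, in both directions. GA2ox1 (AT1G78440) and GA2ox2 (AT1G30040), which inactivate gibberellin, were higher by 4.08 ± 0.19 and 3.18 ± 0.17, and so was the biosynthetic gene GA3ox2 (AT1G80340) (2.0 ± 0.20). In the gibberellin and brassinosteroid list 7 of 24 genes were higher and 2 lower, or 7 and 5 adjusted over the list alone (camera, adjusted p = 0.0014; adjusted p = 0.061 with an estimated correlation). Auxin-responsive genes were lower, IAA6 (AT1G52830) by -1.17 and IAA4 (AT5G43700) by -0.70, against rises of the auxin carrier PIN4 (AT2G01420) (1.49) and the conjugating enzyme GH3.6 (AT5G54510) (1.43). The auxin list had 5 of 30 genes higher and 14 lower, or 7 and 17 adjusted over the list alone (camera, adjusted p = 0.001; adjusted p = 0.25 with an estimated correlation). The wall enzyme XTH33 (AT1G10550) was lower by -1.57 ± 0.20. In all, 1005 genes were higher and 797 lower, and of those that differed at least 2-fold 302 were higher and 62 lower.

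**Figure D2:**
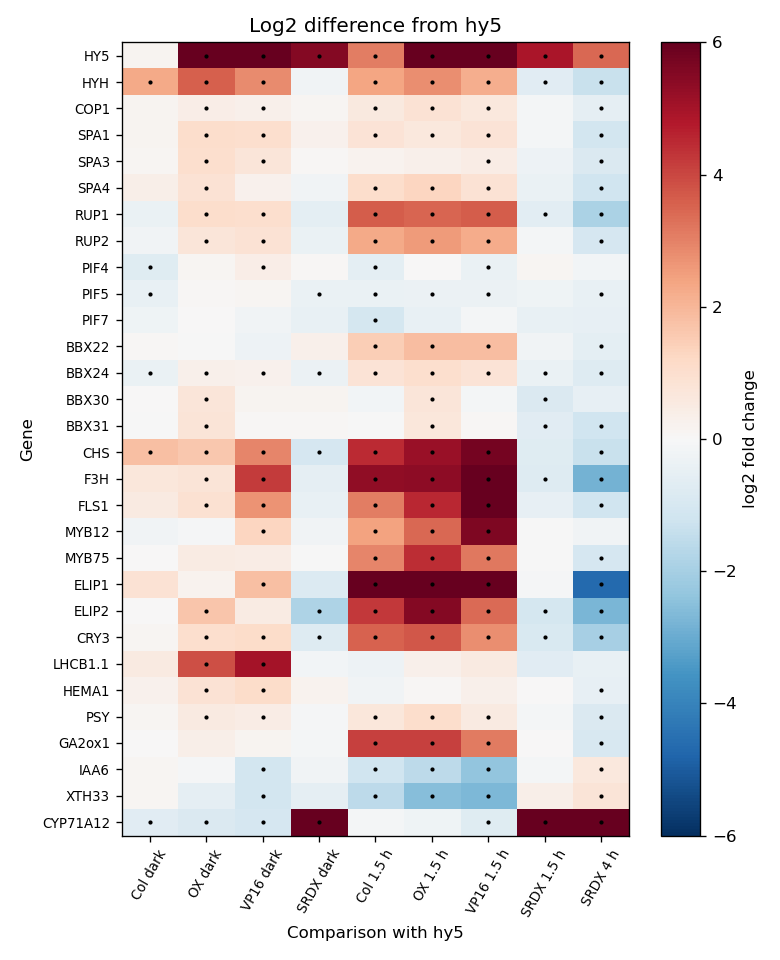
Log2 difference from hy5 (colour, from −6 in blue to 6 in red, values beyond clipped) for 30 genes of light signalling, pigment, photosynthesis, hormone and stress lists (down the side) in the 9 comparisons of Col, OX, VP16 and SRDX with hy5 (across). A dot marks an adjusted p below 0.05. ELIP1 is at 7.74 in Col at 1.5 h and at -4.69 in SRDX at 4 h.

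OX against hy5 in the dark compares seedlings with much and with little HY5 transcript, both 3 days after the hour of light. Light-harvesting genes stood high. LHCB1.1 (AT1G29920) was at 87.6 ± 39.6 CPM against 4.61 ± 0.999 in hy5 (log2 3.88 ± 0.27) and LHCB1.4 (AT2G34430) was higher by 5.94 ± 0.43. These family members share long stretches of sequence, so that reads may be split between them. HYH was higher by 3.57 ± 0.15, SPA1 by 1.03 ± 0.12 and SPA3 (AT3G15354) by 1.02 ± 0.13. In the photosynthesis list 30 of 40 genes were higher and 2 lower, or 31 and 2 adjusted over the list alone (camera, adjusted p = 1.0e-23; adjusted p = 0.16 with an estimated correlation). In the light-signalling list 11 of 29 were higher and 1 lower, or 12 and 1 adjusted over the list alone (camera, adjusted p = 6.0e-10; adjusted p = 0.023 with an estimated correlation). The list holds HY5 itself, and without it 10 of 28 genes were higher and 1 lower, or 11 and 1 adjusted over the list alone (camera, adjusted p = 1.6e-07; adjusted p = 0.069 with an estimated correlation). QQS was lower (-5.82 ± 0.20), as was ZFP5 (AT1G10480), a zinc-finger regulator of hair cells (-2.38 ± 0.14). All 7 heat shock genes were lower, and 7 adjusted over the list alone, with a median of -1.32 (camera, adjusted p = 1.1e-08; adjusted p = 0.058 with an estimated correlation). Mitochondrially encoded genes took 0.432 ± 0.146% of the reads in dark OX and 0.125 ± 0.0233% in dark hy5, and 0.316 ± 0.0487% and 0.123 ± 0.0162% at 1.5 h (SD, n = 3 each). Of all genes 1323 were higher and 1330 lower, and the total of 2653 was 1589 without dark hy5 replicate 1, 1727 without replicate 2 and 1496 without dark OX replicate 2.

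In light OX stood above hy5 in flavonoid and ELIP genes, as Col did. ELIP1 was higher than in hy5 by 7.71 ± 0.35, ELIP2 (AT4G14690) by 5.50 ± 0.24, F3H by 5.38 ± 0.19 and MSRB6 (AT4G04840), a methionine sulfoxide reductase, by 5.27 ± 0.35. MYB75 was higher by 4.43 ± 0.24, GA2ox1 by 4.09 ± 0.19, RUP1 by 3.51 ± 0.18 and COP1 by 0.85 ± 0.09. The flavonoid list had 18 of 23 genes higher and 1 lower, or 19 and 1 adjusted over the list alone (camera, adjusted p = 2.9e-24; adjusted p = 0.0011 with an estimated correlation). XTH33 was lower by -2.54 ± 0.20. The photosynthesis list had 5 of 40 genes higher and 1 lower, or 5 and 0 adjusted over the list alone (camera, adjusted p = 0.066; adjusted p = 0.73 with an estimated correlation; 11 higher and 0 lower without hy5 replicate 1), and LHCB1.1 was at 976 ± 124 CPM in OX and 813 ± 202 CPM in hy5. In all 2484 genes were higher and 2482 lower.

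VP16 against hy5 in the dark shows the fusion with the activation domain. F3H was at 33.3 ± 4.89 CPM against 0.841 ± 0.223 in hy5 (log2 4.22 ± 0.19), FLS1 (AT5G08640), flavonol synthase, was higher by 2.69 ± 0.22, and CHS by 2.92 ± 0.24. Photosynthesis genes were high again: LHCB1.4 by 6.57 ± 0.43, LHCB1.1 by 5.0 ± 0.27, and 35 of the 40 genes higher and 0 lower, or 35 and 0 adjusted over the list alone (camera, adjusted p = 1.8e-32; adjusted p = 0.075 with an estimated correlation). Chlorophyll genes such as HEMA1 (AT1G58290) (1.08) and CHLH (AT5G13630) (1.06) followed, with 9 of 20 higher and 0 lower, or 11 and 0 adjusted over the list alone (camera, adjusted p = 3.0e-06; adjusted p = 0.081 with an estimated correlation). Lower were CYP705A5 (AT5G47990), an enzyme of the root triterpene thalianol pathway (-2.92 ± 0.17), the sulphate-reducing enzymes APR3 (AT4G21990) (-1.94) and APR1 (AT4G04610) (-1.57), and the nitrate transporter NRT1.1 (AT1G12110) (-1.07). The nitrogen and sulphur list had 2 of 10 higher and 6 lower, or 3 and 6 adjusted over the list alone (camera, adjusted p = 0.0046; adjusted p = 0.081 with an estimated correlation). Handling-related groups moved beside them. All 7 heat shock genes were lower, and 7 adjusted over the list alone, with a median of -1.50 (camera, adjusted p = 6.5e-09; adjusted p = 0.074 with an estimated correlation), and 5 of 7 defence and wounding genes were lower, or 5 adjusted over the list alone (camera, adjusted p = 2.8e-04; adjusted p = 0.081 with an estimated correlation). In total 2180 genes were higher and 2188 lower.

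In light VP16 held the highest CHS, F3H and FLS1 transcripts of the 12 groups, with CHS at 541 ± 119 CPM against 229 ± 49.4 in Col, and F3H, FLS1 and MYB12 higher than in hy5 by 6.5 ± 0.19, 6.0 ± 0.22 and 5.58 ± 0.17. Of the 23 flavonoid genes 22 were higher and 1 lower, and the same numbers adjusted over the list alone (camera, adjusted p = 9.3e-34; adjusted p = 1.5e-04 with an estimated correlation). The lower one, MYBL2 (AT1G71030) (-1.20 ± 0.16), represses anthocyanin genes. Growth genes were lower, IAA6 by -2.38, XTH33 by -2.68 and EXPA11 (AT1G20190) by -1.61. The auxin list had 3 of 30 higher and 20 lower, or 3 and 20 adjusted over the list alone (camera, adjusted p = 6.2e-10; adjusted p = 0.024 with an estimated correlation), and the cell wall list 2 of 21 higher and 14 lower, or 3 and 14 adjusted over the list alone (camera, adjusted p = 1.3e-05; adjusted p = 0.038 with an estimated correlation). Root hair genes went both ways, with EXPA7 (AT1G12560) higher by 1.74 and LRX1 (AT1G12040) by 1.60, in a list with 6 of 10 higher and 3 lower, or 6 and 3 adjusted over the list alone (camera, adjusted p = 0.093; adjusted p = 0.48 with an estimated correlation). Heat shock genes, lower in the dark, had 5 of 7 higher and 2 lower, or 5 and 2 adjusted over the list alone (camera, adjusted p = 0.2; adjusted p = 0.63 with an estimated correlation), and 3 higher without hy5 replicate 3 and 2 without VP16 replicate 2. Mitochondrially encoded genes took 0.229 ± 0.0565% of the reads against 0.123 ± 0.0162% in hy5, and chloroplast-encoded genes 0.691 ± 0.0767% against 0.355 ± 0.0850% (SD, n = 3 each). In total 2581 genes were higher and 2324 lower.

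**Figure D3:**
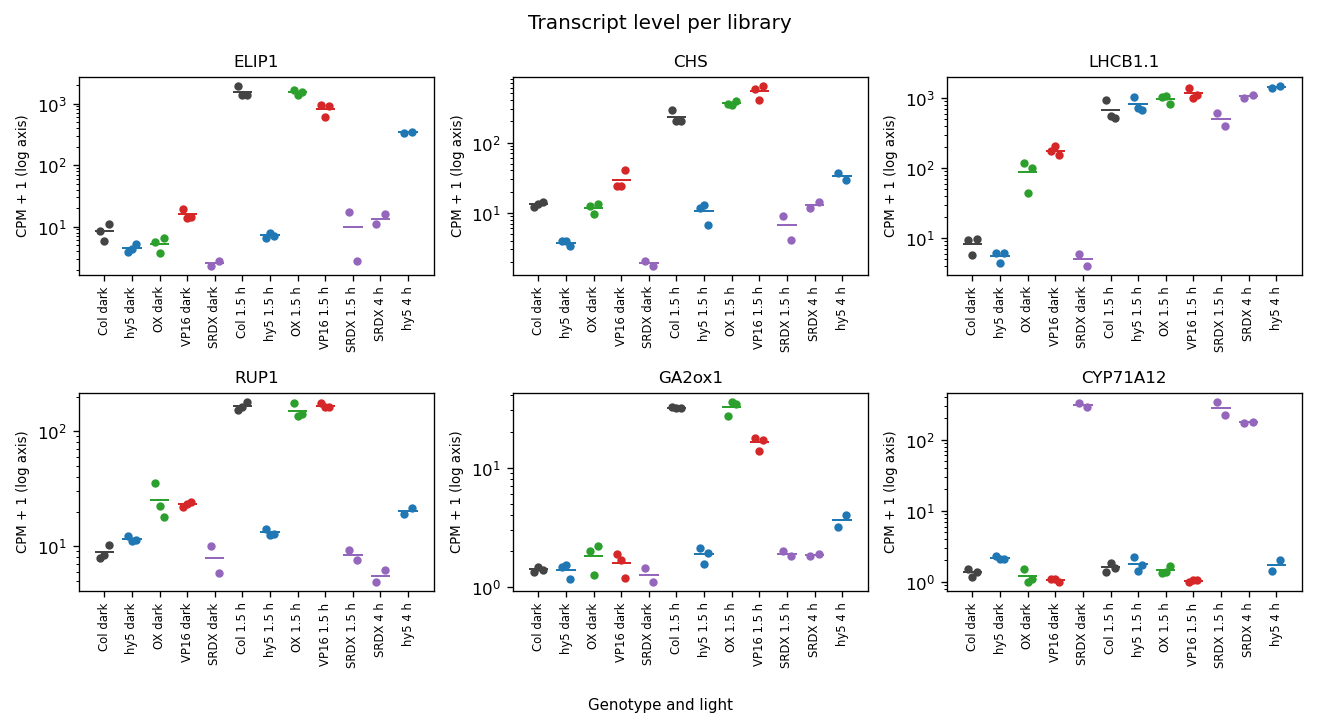
Transcript level per library (points, CPM + 1 on a log axis) of ELIP1, CHS, LHCB1.1, RUP1, GA2ox1 and CYP71A12 in the 12 groups, with group means as bars across. CYP71A12 is high in the 6 SRDX libraries, and LHCB1.1 is high in dark OX and VP16.

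Col, OX and VP16 shared called genes at 1.5 h, and OX and VP16 also in the dark, where Col shared fewer, although all comparisons at 1 time use the same 3 hy5 libraries. At 1.5 h Col and OX shared 752 of the genes called higher and 510 of those called lower, where independent lists would share 127 and 100. Col and VP16 shared 700 and 363, against 132 and 94.1, with 49 and 50 genes called in opposite directions. Across all genes the differences of Col correlated at 0.658 with OX and 0.531 with VP16, where shared controls alone gave 0.500 and 0.496. The covariances were 0.107 and 0.0919, against 0.0122 and 0.0120. For OX and VP16 the shared numbers were 1290 higher and 1131 lower, against 326 and 293, and 26 genes were higher in OX and lower in VP16 and 52 the reverse. In the dark OX and VP16 shared 829 higher and 729 lower genes, against 147 and 148. Dark Col shared 43 and 69 genes with OX, against 11.4 and 15.4, and 63 and 73 with VP16, against 18.7 and 25.3, while 16 and 22 and 31 and 43 were called in opposite directions, against 11.4 and 15.3 for OX and 18.8 and 25.2 for VP16. Across all genes the dark differences of Col correlated at 0.335 with OX and 0.267 with VP16, against 0.501 and 0.499 for shared controls alone. The simulated correlations hold for groups with no change and are set by the group sizes, so a lower value does not by itself measure disagreement. The covariances were 0.0283 and 0.0274, above the simulated 0.0122 and 0.0121. Of the genes lower in OX, 54.8% in the dark and 45.6% at 1.5 h were also lower in VP16, whose fusion carries an activation domain. The covariance of the OX and VP16 differences across genes was 0.0921 in the dark and 0.157 at 1.5 h, where simulated groups with no change against the same controls gave 0.0121 and 0.0121. The 3 hy5 libraries were not split, so part of the excess of shared genes over independent lists may come from the shared controls. The simulated covariances already include that sharing, at the fitted spread.

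SRDX against hy5 shows the fusion with the repression motif. Beside HY5 itself, the highest differences in the dark included cytochrome P450 genes of tryptophan-derived metabolites. CYP71A12 (AT2G30750) was at 311 ± 26.5 CPM against 1.16 ± 0.128 in hy5 (log2 7.18 ± 0.20, n = 2 and 3), CYP82C2 (AT4G31970) was higher by 6.92 ± 0.22 and the methyltransferase gene PXMT1 (AT1G66700) by 5.14 ± 0.20. Lower were ABI3 (AT3G24650), a regulator of seed maturation (-2.57 ± 0.23), the chitinase-like gene AT1G02360 (AT1G02360) (-2.42 ± 0.15) and ELIP2 (-1.84 ± 0.27). At 1.5 h CYP71A12 (7.28 ± 0.20) and CYP82C2 (6.21 ± 0.22) led again. HYH was lower (-0.66 ± 0.17), as were RUP1 (-0.65 ± 0.20), CRY3 (-0.89 ± 0.19) and the B-box gene BBX30 (AT4G15248) (-0.85 ± 0.18). The B-box list had 0 of 15 higher and 5 lower, or 0 and 9 adjusted over the list alone (camera, adjusted p = 5.2e-06; adjusted p = 0.021 with an estimated correlation). The 5 were 2 without hy5 replicate 2 or 3 at 1.5 h, 1 without SRDX replicate 1 and 0 without SRDX replicate 2. The counts were 1022 higher and 889 lower in the dark, and 838 and 441 at 1.5 h. The dark total of 1911 was 732 without dark SRDX replicate 2 and 1189 without dark hy5 replicate 3, and the total of 1279 at 1.5 h was 711 without SRDX replicate 1 and 713 without replicate 2. Without SRDX replicate 2 at 1.5 h HYH, CRY3, BBX30 and RUP1 were not called (adjusted p = 0.479, 0.136, 0.0644 and 0.439), HYH was not called without hy5 replicate 1 (0.0594) or with a pseudocount of 0.25 (0.147), and RUP1 was not called whichever library was left out (hy5 replicate 1, 2 and 3, 0.133, 0.0770 and 0.0796, and SRDX replicate 1, 0.0761) or over genes with a mean of at least 5 CPM (0.0527).

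Markers of stage, tissue and handling differed in SRDX as well. CRC was higher than in hy5, as in Col, by 2.91 ± 0.26 in the dark and 2.32 ± 0.26 at 1.5 h. Its list had 1 of 7 genes higher in the dark and 3 at 1.5 h and 0 lower, or 3 and 4 higher adjusted over the list alone (camera, adjusted p = 0.017 and 0.0021; adjusted p = 0.28 and 0.13 with an estimated correlation). Of 10 root hair and endodermis genes 0 were higher and 2 lower at each time, or 1 and 5 in the dark and 0 and 4 at 1.5 h adjusted over the list alone (camera, adjusted p = 0.0064 and 0.002; adjusted p = 0.23 and 0.13 with an estimated correlation). The 2 were 1 in the dark without hy5 replicate 2 and 0 without SRDX replicate 2, and at 1.5 h 0 without hy5 replicate 1 or 2 or SRDX replicate 1 or 2. Chloroplast-encoded genes took 0.621 ± 0.119% of the reads in SRDX at 1.5 h and 0.355 ± 0.0850% in hy5 (SD, n = 2 and 3). In the dark 0 of 7 heat shock genes were higher and 2 lower, or 0 and 4 adjusted over the list alone (camera, adjusted p = 0.0095; adjusted p = 0.33 with an estimated correlation), and the 2 were 0 without dark hy5 replicate 3 and 1 without SRDX replicate 1 or 2.

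At 4 h SRDX lay below hy5 in ELIP1 and other genes that stood high in Col at 1.5 h. ELIP1 was at 12.5 ± 3.47 CPM in SRDX against 339.8 ± 5.17 CPM in hy5 (log2 -4.69 ± 0.43, n = 2 each). F3H was lower by -2.82 ± 0.24, CRY3 by -2.0 ± 0.21, RUP1 by -1.88 ± 0.21, HYH by -1.34 ± 0.19, SPA1 by -1.09 ± 0.14, and COP1 by -0.55 ± 0.11. Photoprotection genes had 0 of 7 higher and 6 lower, and 6 adjusted over the list alone (camera, adjusted p = 5.6e-10; adjusted p = 3.6e-04 with an estimated correlation). Carotenoid genes such as PSY (AT5G17230) (-0.86) and ZEP (AT5G67030) (-0.86) had 0 of 9 higher and 8 lower, and 8 adjusted over the list alone (camera, adjusted p = 1.2e-07; adjusted p = 9.4e-04 with an estimated correlation). The B-box list had 0 of 15 higher and 8 lower, or 11 adjusted over the list alone (camera, adjusted p = 1.5e-05; adjusted p = 0.016 with an estimated correlation), and the flavonoid list 1 of 23 higher and 11 lower, or 1 and 13 adjusted over the list alone (camera, adjusted p = 6.5e-05; adjusted p = 0.15 with an estimated correlation). CYP71A12 was still higher (6.69 ± 0.22), beside defence genes with 4 of 7 higher and 0 lower, or 5 and 0 adjusted over the list alone (camera, adjusted p = 7.3e-05; adjusted p = 0.087 with an estimated correlation), and seed storage genes with 4 of 7 higher and 0 lower, or 6 and 0 adjusted over the list alone (camera, adjusted p = 2.7e-04; adjusted p = 0.087 with an estimated correlation). The 4 seed storage genes were 2 without SRDX replicate 1 and 1 without hy5 replicate 1. In all 1623 genes were higher and 1900 lower, and the total of 3523 was 2305 without SRDX replicate 1 and 2074 without replicate 2.

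VP16 and SRDX, which carry opposite domains on the same protein, were compared for opposite changes. PXMT1 was at 1.67 ± 0.635 CPM in dark VP16, 15.6 ± 2.77 in hy5 and 579.8 ± 15.7 in SRDX, and IGMT1 (AT1G21100), a methyltransferase of indole glucosinolates, AIR1 (AT4G12550), a lipid-transfer-like gene of roots, and MLP329 (AT2G01530), a major latex-like gene, were also lower in VP16 and higher in SRDX. XTH14 (AT4G25820), a wall-modifying enzyme of root hairs, was higher in VP16 by 1.89 ± 0.22 and lower in SRDX (-1.19 ± 0.25). In the dark 93 genes were higher in VP16 and lower in SRDX and 158 the reverse, where independent lists would share 98.5 and 114. In the same direction they shared 279 higher and 318 lower genes, against 113 and 98.8. At 1.5 h 152 genes were higher in VP16 and lower in SRDX and 232 the reverse, against 57.8 and 98.9. In the same direction VP16 and SRDX then shared 119 higher and 110 lower genes, against 110 and 52.1. OX, which carries no added domain, and Col also had genes called opposite to SRDX at 1.5 h. For OX 129 were higher and lower in SRDX and 160 the reverse, against 55.6 and 106. In the same direction OX and SRDX shared 73 and 97. For Col the opposite calls were 119 and 45, against 22.5 and 33.9, with 49 and 33 shared. The covariances with SRDX were -0.00936 for OX and -0.00575 for Col, so opposite calls at 1.5 h were not particular to the activation domain. The covariance of the VP16 and SRDX differences was 0.0277 in the dark and -0.00856 at 1.5 h, where unchanged groups against the same controls gave 0.0122 and 0.0122. The correlation of the VP16 and SRDX differences was 0.177 in the dark and -0.0466 at 1.5 h, against 0.448 for shared controls alone. That simulated value holds for groups with no change and is set by the group sizes, so a lower value does not by itself measure disagreement. The controls were not split, so part of the excess in one direction over independent lists may come from them. The simulated covariances already include this sharing, at the fitted spread. The opposite counts in the dark fell to 44, 54 and 51 (from 93) and to 104, 93 and 96 (from 158) without dark hy5 replicate 1, 2 and 3, and to 40 (from 93) without dark SRDX replicate 2. At 1.5 h the first count, 152, was 96 and 92 without hy5 replicate 1 and 2 and 89 and 60 without SRDX replicate 1 and 2, and the second, 232, was 138 without SRDX replicate 1.

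Set against each other directly, with no hy5 library in the comparison, VP16 lay above SRDX at 1.5 h by 6.43 ± 0.27 for CHS, 6.89 ± 0.39 for ELIP1 and 4.30 ± 0.20 for RUP1, and below it by -3.03 ± 0.23 for XTH33. The ELIP1 value rests on 2 SRDX libraries that differ, and was 8.21 without SRDX replicate 1 and 5.56 without replicate 2. The flavonoid list had 22 of 23 genes higher in VP16 and 1 lower, and the same adjusted over the list alone (camera, adjusted p = 4.1e-27; adjusted p = 5.9e-04 with an estimated correlation). In the dark the photosynthesis list had 38 of 40 higher in VP16 and 0 lower, or 39 and 0 adjusted over the list alone (camera, adjusted p = 2.3e-39; adjusted p = 0.075 with an estimated correlation). Called genes numbered 1916 higher and 2033 lower in the dark and 3029 and 2857 at 1.5 h, and the dark total of 3949 was 2475 without dark SRDX replicate 2.

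The response to 1.5 h of light was measured within each genotype. In Col ELIP1 rose by 7.57 ± 0.35, F3H by 6.92 ± 0.19, LHCB1.1 by 6.33 ± 0.27 and BBX32 by 6.32 ± 0.15, and PIL1 (AT2G46970), a shade marker kept high by PIF factors in the dark, fell (log2 -3.61 ± 0.14). In hy5 LHCB1.1 rose by 7.17 ± 0.27 and PIL1 changed by -3.45 ± 0.14, while ELIP1 at 0.70 and RUP1 at 0.19 were not called. The sugar-starvation gene DIN6 (AT3G47340), an asparagine synthetase, fell in Col and hy5 (-2.36 and -2.23), and its list had 0 of 4 genes risen and 3 fallen in Col, and 3 adjusted over the list alone (camera, adjusted p = 3.4e-04; adjusted p = 0.073 with an estimated correlation). The photosynthesis list had 37 of 40 risen in Col and 37 in hy5, or 39 in each adjusted over the list alone (camera, adjusted p = 3.8e-27 and 3.0e-31; adjusted p = 0.051 and 0.049 with an estimated correlation). In OX and VP16, where these genes were already high in the dark, LHCB1.1 rose by 3.58 ± 0.27 and 2.71 ± 0.27. Called genes numbered 7051 in Col, 6308 in hy5, 9090 in OX, 8772 in VP16 and 5231 in SRDX, the last 3352 without SRDX replicate 1 at 1.5 h. By 4 h hy5 had changed 10002 genes and SRDX 9176, and ELIP1 had risen in hy5 by 6.27 ± 0.39 and in SRDX by 2.39 ± 0.43.

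**Figure D4:**
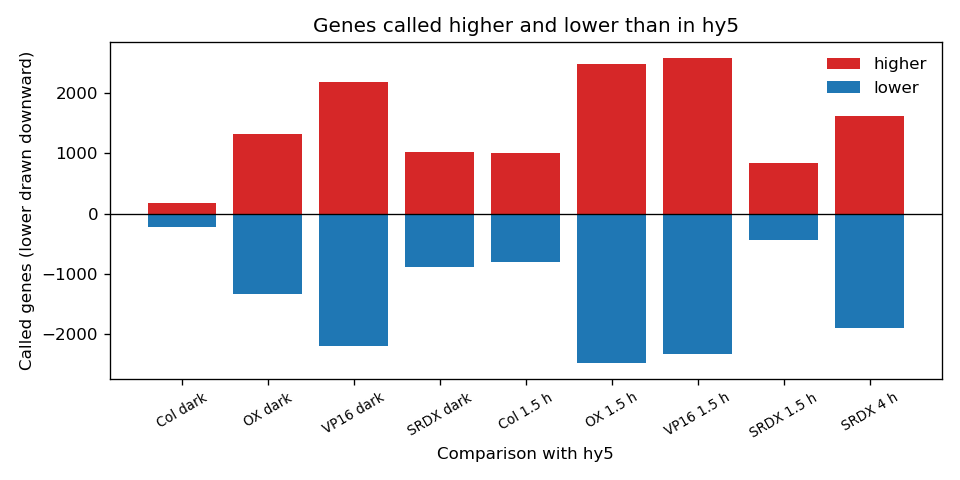
Number of genes called higher (upward bars) and lower (downward bars) than hy5 in the 9 comparisons of Col, OX, VP16 and SRDX, from 19685 genes at an adjusted p below 0.05. The Col comparison grows from 397 genes in the dark to 1802 at 1.5 h.

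Whether the light response differs from that of hy5 was tested as an interaction. For ELIP1 it differed by 6.86 ± 0.49 in Col, 7.49 ± 0.49 in OX and 5.0 ± 0.49 in VP16, and for F3H by 4.66 ± 0.27, 4.61 ± 0.27 and 2.28 ± 0.27. LHCB1.1 differed the other way, by -3.59 ± 0.38 in OX and -4.46 ± 0.38 in VP16. In SRDX TAT3 (AT2G24850), a tyrosine aminotransferase of jasmonate response, differed by 3.6 ± 0.25, and it was not called with edgeR (adjusted p = 0.97) or DESeq2 (0.0501). F3H was not called in VP16 with edgeR (0.0553). The number of genes with a different response was 790 in Col, 2110 in OX, 1668 in VP16 and 25 in SRDX, and this last was 14 without SRDX replicate 1 at 1.5 h. In Col the change with light, with its sign, lay above that of hy5 for 571 of them and below it for 219, and the flavonoid list had 16 of 23 above and 0 below, and 16 adjusted over the list alone (camera, adjusted p = 8.1e-33; adjusted p = 1.8e-04 with an estimated correlation). In VP16 the heat shock list had 6 of 7 above and 0 below, or 7 adjusted over the list alone (camera, adjusted p = 2.2e-11; adjusted p = 0.022 with an estimated correlation).

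The fold changes against hy5 that the authors deposited were compared with those computed here, gene by gene. Across genes, which are not independent replicates, Spearman's rho lay between 0.984 and 0.992 in the 9 comparisons, and every gene called here had the same sign in both. The slope of the differences computed here on the deposited ones lay between 0.528 and 0.723, and between 0.815 and 0.923 over the genes with a mean of at least 5 CPM. Of the 215 list tests that passed by camera among 374, 65 also passed with an estimated correlation, 58 of them upward.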

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

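The tests of light exposure, of a defence response and of a single odd library were chosen only after the results they measure were seen, as were the interaction at 4 h, the share over 302 genes and the grouping of splits by crossed names, and the others were written first.

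The results here differ between groups by an interaction test, the light response of a genotype against that of hy5. It called 790 genes in Col, 2110 in OX, 1668 in VP16 and 25 in SRDX, and at 4 h 1983 genes in SRDX, which were 1242 without SRDX replicate 1 and 1171 without replicate 2. For ELIP1 the response differed by 6.86 in Col, 7.49 in OX and 5.0 in VP16, for F3H by 4.66, 4.61 and 2.28, for LHCB1.1 by -3.59 in OX and -4.46 in VP16, and for TAT3 by 3.6 in SRDX.

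Other splits of the same libraries into groups of the same sizes were counted. For the interactions, 100 splits were drawn, and 7 of 100 called as many genes as the real groups in Col (highest other 2119 against 790), 7 in OX (5921 against 2110) and 12 in VP16 (6745 against 1668). The splits with many more calls point to a structure of the samples: in 6 of the 7, 6 of the 7 and 11 of the 12, all but the real one, the genotype names were crossed between dark and light, which turns a difference of responses into a sum of genotype effects. Such splits cannot stand for chance, and the 100 together leave it undecided. Among the 48 splits with names not crossed only the real one called as many, and the highest others called 784, 1855 and 1417. These highest others kept all 3 libraries of the genotype at 1.5 h and 2 of its 3 in the dark. They nearly repeat the real grouping and cannot stand for chance either. Splits that kept 2 of 3 at each light called 0 or 1 genes. For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05, and in each only 1 split, the real one, called as many. The real and highest other numbers were 397 and 0 for Col against hy5 in the dark, 1802 and 1 at 1.5 h, 2653 and 0 for OX in the dark, 4966 and 2 at 1.5 h, 4368 and 0 for VP16 in the dark, 4905 and 1 at 1.5 h, and, for light against dark, 7051 and 0 in Col, 6308 and 1 in hy5, 9090 and 5 in OX and 8772 and 1 in VP16.

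Photosynthesis genes stood high in dark OX and VP16, as if these seedlings had met light during the 3 dark days. Genes that fell at least 4-fold with light in Col argue against such exposure shortly before harvest. Over 68 of them, dark OX differed from dark hy5 by a median 0.0891 of the light response (bootstrap interval 0.0415 to 0.109). For VP16 the median was 0.0807 (0.0267 to 0.172), and both lay below the limit of 0.25 set for this ratio. Exposure earlier in the dark days stays open, because the return of these genes in later darkness was not measured. Read depth is argued against by thinning the dark libraries to equal reads. The photosynthesis genes called higher numbered 35 before and 35 after in VP16, and 30 before and 31 after in OX. An effect of abundant HY5 on the photosynthesis genes, as the design names, stays open as a hypothesis, though HY5 protein was not measured. In dark Col, whose HY5 transcript was not called different from that of hy5, some photosynthesis genes were lower than in hy5, as given above. A lasting response to the hour of light at germination that differs by genotype was not tested and stays open too.

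HY5 and ELIP1 stood high in hy5 at 4 h, at 82.2 and 339.8 CPM, and no Col library at 4 h exists in the design to compare. If wild-type seedlings were among these samples, genes high in hy5 and low in Col would move toward Col. Over 7 such genes the median share of the way was 0.496, above the 0.2 set for it. Its bootstrap interval over genes was 0.301 to 1.04, which leaves out the spread between libraries, and single genes ranged from 0.120 to 1.15. Over the 302 genes at least 2-fold higher in Col at 1.5 h the median share was 0.213, with 102 below 0.1 and 34 above 1, where an admixture alone would give 1 common share if Col stayed at its level of 1.5 h. An exchange of whole samples is not decided by the interval over the 7 genes, whose upper end is 1.04. Over the 302 genes an exchange would give shares near 1 if Col stayed at its level of 1.5 h. On that condition their median of 0.213 argues against an exchange, for these genes. QQS stood at 32.1 CPM in hy5 at 4 h, against 0.519 in dark Col and 0.643 in Col at 1.5 h. A later light response of hy5, in which each gene may change by its own amount, could give such values, and admixture and a later response both stay open, which bears on every difference between SRDX and hy5 at 4 h.

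CYP71A12, CYP82C2 and PXMT1 stood high in SRDX in the dark and in light. In the dark the 7 measured genes of the defence, wounding and touch list had a median of 0.26 (range -0.43 to 0.55). That argues against a response of these 7 genes in the dark, while at 1.5 h and 4 h their medians were 0.58 and 1.21. A defence response that does not move these 7 genes was not tested and stays open. A single odd library is argued against by all 6 SRDX libraries, of which the lowest was at least 18.9 times the highest other library for each gene. An effect of the fusion protein and an effect of the insertion site in this 1 line were not tested and stay open.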

How the results depend on the processing

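The filter at a mean of 5 CPM was chosen after seeing the data, except for the deposited fold changes, and the other settings were planned. The 26 counts were run under every setting, and the level of HY5 and 134 gene values under all but the fold limit and "no filter" (124 values at a mean of 5 CPM). No gene value turned, and HY5 was called as before except for OX at 1.5 h against dark in a fit on the compared groups alone (-0.63, adjusted p = 0.157). The list tests were run with the estimated correlation and the block, where none of the 215 that passed turned, and the sign shared with the deposited fold changes at a mean of 5 CPM alone, where it stayed the same. Median-of-ratios scaling moved no count by over 1.5 times, and "no filter" leaves the same genes and tests nothing. The calls of 15 gene values were lost in at least 1 setting, 5 with edgeR, 1 with DESeq2, 3 with a pseudocount of 0.25, 2 on the compared groups alone, 1 at a mean of 5 CPM and 13 when a library was left out. Among them OLEO2 and CCA1 (Col against hy5, dark), HRGP1 and CHS (SRDX, dark) and BBX31 and BBX32 (SRDX, 1.5 h) were taken out of the report once that was seen. Low depth limits genes near the floor, and where 1 library of 2 is left it is assumed to vary like the other groups. The cause was not tested, except that a fold limit and a filter leave fewer genes by construction.

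A fold of at least 2 left, for Col, OX, VP16 and SRDX against hy5, 69, 279, 585 and 354 calls in the dark and 364, 780, 1002 and 422 at 1.5 h, and 894 for SRDX at 4 h. For light against dark it left 1533 in Col, 1278 in hy5, 2136 in OX, 2029 in VP16 and 1252 in SRDX, at 4 h 2868 in hy5 and 2507 in SRDX, for the interactions 342, 646 and 611 in Col, OX and VP16, for VP16 against SRDX 942 and 1646, and for opposite calls 7 and 24 in the dark and 14 and 39 at 1.5 h. A fit on the compared groups alone gave 1648 for OX in the dark, 2186 for SRDX at 1.5 h, 2062 at 4 h, 14 for the SRDX interaction and 252 genes higher in VP16 and lower in SRDX at 1.5 h. The SRDX interaction, 25 in the report, was 11 with a pseudocount of 0.25, 4 with edgeR, 9 with DESeq2 and 3 at a mean of 5 CPM. DESeq2 gave 609 for Col in the dark and the 5 CPM filter 806 for SRDX at 1.5 h. Of 215 list tests 65 passed with an estimated correlation.

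With each library left out in turn the counts ranged from 141 to 512 for Col in the dark, 1496 to 3040 for OX in the dark, 732 to 1678, 711 to 1045 and 2074 to 2973 for SRDX in the dark, at 1.5 h and at 4 h, 3352 to 4446 for the SRDX light response, 14 to 31 for its interaction and 2475 to 3594 for VP16 against SRDX in the dark. Opposite calls ranged from 40 to 80 and 93 to 135 in the dark and from 60 to 143 and 138 to 248 at 1.5 h.

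With the replicate number as a block no count moved by over 1.5 times and no gene call was lost: Col against hy5 in the dark, the comparison with correlated pairs, had 468 calls and VP16 4553. Of the 215 list tests 1 was lost and 2 were gained under the block, none of them printed in the report. Each library correlated best with its own number in Col against hy5 in the dark and at 1.5 h, a hint from the data and not from the design.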

Other observations

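The comparisons with OX and the test of genes that SRDX lowers were chosen only after related results were seen, and the test of the later rise was written first.

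Set against OX, which carries HY5 without an added domain, VP16 was higher for flavonoid genes although its transgene transcript was lower. At 1.5 h MYB12 was higher by 2.14 ± 0.17, FLS1 by 1.49 ± 0.22 and F3H by 1.11 ± 0.19 (n = 3 each), while CHS at 0.55 was not called and MYB75 was lower (-1.27 ± 0.24). The flavonoid list had 12 of 23 genes higher and 4 lower, or 13 and 4 adjusted over the list alone (camera, adjusted p = 3.0e-04; adjusted p = 0.21 with an estimated correlation). Auxin genes were lower in VP16 than in OX in the dark, IAA6 by -1.02 ± 0.16, with 0 of 30 higher and 14 lower, or 16 adjusted over the list alone (camera, adjusted p = 2.7e-09; adjusted p = 0.088 with an estimated correlation). Root hair genes were higher, EXPA7 by 1.72 ± 0.25 and LRX1 by 2.06 ± 0.34, with 5 of 10 higher and 0 lower, or 5 and 1 adjusted over the list alone (camera, adjusted p = 3.7e-04; adjusted p = 0.12 with an estimated correlation). In all 2237 genes differed in the dark, or 1411 without dark VP16 replicate 3, and 4301 at 1.5 h. Col differed from OX in 3195 genes in the dark, or 1923 without dark Col replicate 1, and in 3919 at 1.5 h, or 2457 without Col replicate 2 and 2418 without OX replicate 2.

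SRDX lay below OX in photoprotection genes in light. CRY3 was lower by -4.63 ± 0.19, ELIP1 by -7.78 ± 0.39 and HYH by -3.47 ± 0.17 (n = 2 and 3; ELIP1 -9.11 without SRDX replicate 1 and -6.46 without replicate 2), and the photoprotection list had 0 of 7 higher and 7 lower, and 7 adjusted over the list alone (camera, adjusted p = 6.6e-14; adjusted p = 4.4e-05 with an estimated correlation). Much of these gaps lay between OX and hy5. ELIP1 was 7.71 ± 0.35 higher in OX than in hy5, and SRDX held 16.1 and 1.73 CPM against 5.59 to 6.95 CPM in hy5. In SRDX CRY3 and HYH lay below hy5 by -0.89 ± 0.19 and -0.66 ± 0.17, with the limits given above. For SRDX against OX in the dark the photosynthesis list had 0 of 40 higher and 34 lower, or 36 adjusted over the list alone (camera, adjusted p = 1.6e-28; adjusted p = 0.13 with an estimated correlation). Called genes numbered 3331 in the dark, or 1876 without dark SRDX replicate 2, and 6733 at 1.5 h, or 4405 without SRDX replicate 1.

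A hypothesis is that the SRDX fusion lowers genes that HY5 raises. Of 302 genes at least 2-fold higher in Col than in hy5 at 1.5 h, 187 were called lower and 14 higher in SRDX than in hy5 at 4 h, where independent lists would share 29.1 of those lower, a ratio of 6.42, and these comparisons share no library. At 1.5 h 54 of the 302 were called lower and 13 higher, a ratio of 7.98 for those lower. In the dark 32 were called lower and 16 higher, a ratio of 2.35. The larger ratio at 1.5 h thus covers fewer of the 302 genes than the ratio at 4 h. The SRDX comparison at 1.5 h shares its hy5 libraries with the Col comparison. A further hypothesis is that the SRDX effect follows the later rise of these genes in hy5. With separate hy5 libraries on each side, the rise from 1.5 h to 4 h and the SRDX effect at 4 h had a mean Spearman rho of -0.414 over the 302 genes (-0.360 and -0.468 for the 2 ways to part the libraries) and of -0.207 over all other genes (-0.107 and -0.307 in the same order). The hy5 level at 4 h enters both sides with opposite sign, so a negative rho is partly built in and cannot decide for this hypothesis. Both hypotheses predict the overlap and the negative rho. So might wild-type seedlings among the hy5 samples at 4 h, tested above without a decision, with a median share of 0.496 over 7 genes and 0.213 over these 302. HY5 binding was not measured here.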
